A study of Homo sapiens with 9 samples.

How the data were processed

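The data are 9 RNA libraries of SKBR3, an established human breast cancer cell line with an amplified ERBB2 (HER2) gene. Cells were transfected with 10 nM siRNA in a lipid reagent and treated for 48 h. 3 libraries received a non-targeting control siRNA, 3 received the first PVRL4 siRNA (siRNA 1) and 3 received the second (siRNA 2), with groups and replicate numbers taken from the sample titles. Per the labels' protocols, the control siRNA came from the ON-TARGETplus line of Horizon Discovery and both PVRL4 siRNAs from Integrated DNA Technologies, so control and PVRL4 siRNAs differ in supplier as well as in sequence. The siRNA sequences and the chemical form of the duplexes were not given in the sources used here.

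Per the labels' protocols, the authors made libraries from 100 ng of total RNA with an Ion AmpliSeq transcriptome kit, which amplifies 1 short amplicon per gene. Amplicon reads carry no molecular identifiers, so floors given in reads cover counting error only. The confidence intervals given for PVRL4 come from limma's estimate of the spread between libraries. A gene is measured at its amplicon alone, and a close paralog or an overlapping transcript that shares the amplicon cannot be told apart from it. The authors deposited 1 table of RPM values (reads of a gene scaled to the reads of its library) for 20812 genes, each with a gene symbol and an amplicon name. Values of each library sum to the same total, so differences in total RNA per cell are removed by that unit. The genome build was hg19, per the submitters' processing notes; the aligner and the counting tool were not given in the sources used here.

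The RPM steps gave back whole reads. In every library 100% of values were whole multiples of the value of 1 read within a tolerance of 0.1 read, with library totals of 10017130 to 10707777 reads. 1 read was worth 0.0934 to 0.0998 RPM, and a floor of 3 reads lay at 0.280 to 0.299 RPM. Between 13758 and 13996 genes had a read in each library. Pairs of libraries of the same group differed by more than counting noise, with a chi-square per degree of freedom of 8.95 to 23.7 over genes with a mean of at least 10 reads, so no library was treated as a copy of another. The labels do not say whether the replicates are separate cultures, so p-values measure the spread between these samples, which may be technical.

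Tests were run on log2(RPM + 1) with limma 3.58.1 in R 4.3.3, with a trended prior variance, for the 11158 genes with a mean of at least 1 RPM over the 9 libraries. The 3 groups shared 1 estimate of the spread, and 3 contrasts were taken: each PVRL4 siRNA against control, and siRNA 2 against siRNA 1. The series names siCTRL and siPVRL4 without a siRNA number, so the 6 PVRL4 siRNA libraries were also pooled against the 3 controls in a 2-group fit. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 changes are on the log2(RPM + 1) scale, which understates the change of genes near 1 RPM. Unless another tool is named, an adjusted p is limma's. PVRL4 was also compared by an exact permutation test of 3 against 3 libraries, which cannot go below p = 0.1.

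In total, 40 gene lists were written from textbook knowledge, covering adhesion, receptor signalling, cell cycle, stress, metabolism, interferon and markers of other cell types. The 36 lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation and fry were run beside it. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone.

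Named genes follow a rule. PVRL4, ERBB2, ERBB3, FOS, FOSB, FOSL1, FOSL2 and JUN are always named. For genes past the threshold with both siRNAs the rule takes up to 12 higher and 12 lower. For each contrast it takes the 8 higher and the 8 lower genes with the largest change among those past the threshold, with a mean of at least 10 RPM over the 6 libraries compared and no overlap between the groups. Of each described list, up to 4 members with the smallest adjusted p are named, or up to 2 where none passed. Some genes that the rule selects are not reported here. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined.

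The replicate numbers pair the samples. Deviations from the group means correlated at 0.252 to 0.417 in all 9 pairs of libraries that share a number across groups, against -0.340 to -0.0275 in the other 18 pairs, and each of the 9 libraries correlated best with libraries of its own number. The pairing comes from the numbers in the sample titles. The fit with the replicate number as a block is given beside a result where it changes a call or moves a count by over 1.5 times.

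Alternatives were other pseudocounts (0.1 and 5), no filter and a filter at 5 RPM, median-of-ratios, TMM and quantile scaling, the replicate block, fits on the 6 libraries compared, limma without a trend, stricter thresholds, each library left out in turn, and edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 on the recovered whole reads. The edgeR fit with the replicate block was chosen after seeing the data. Shared controls were handled by 100 simulations of unchanged groups against the same 3 control libraries; 3 controls cannot be split into 2 sets of at least 2 libraries.

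The fits were tested on simulated reads for 11158 genes, of which 200 were changed, 50 at each fold size. For siRNA 1 against control limma found 30% of genes changed 1.5-fold, 76% of those changed 2-fold and 98% of those changed 4-fold, and it called 9 of 10814 unchanged genes. For siRNA 2 against control it found 42%, 70% and 96%, with 11 of 10815 unchanged genes called. For siRNA 2 against siRNA 1 it found 36%, 74% and 96%, with 9 of 10811 called.

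For sequence searches, genes were matched to GENCODE 29 transcripts on GRCh38 through their Entrez numbers, and the longest 3' UTR of a gene was taken. Of the 11158 genes, 10438 (93.5%) had a 3' UTR to search. The presence of each of 16164 words of 7 bases was tested against the rank-transformed log2 changes. Words were planted with a log2 change of -0.1 or -0.2. In 10 simulations per setting the planted word ranked first each time, and 0 to 2 of 10 scans without a planted word passed the Bonferroni threshold. Smaller changes were not planted. The first-ranked words of the data went with smaller shifts of the median: -0.033 with AGTCTGA against 0.019 without (siRNA 1), and -0.084 with TGGTCAC against -0.014 without (siRNA 2). Coordinates are given for GRCh38, from that annotation.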

Results

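SKBR3 cells, a human breast cancer line that carries an amplified ERBB2 gene, were treated for 48 h with a control siRNA or with 1 of 2 siRNAs against PVRL4, and their messenger RNA was measured by amplicon sequencing. PVRL4 (NECTIN4 in current annotation) encodes nectin-4, a cell adhesion molecule that is the target of an antibody-drug conjugate. Each of the 3 groups had 3 libraries of 10017130 to 10707777 reads. The series concerns the control of PVRL4 expression by FOS family proteins, and this part of it compares gene expression with and without PVRL4 siRNA. Values are means in RPM with their SD over the 3 libraries of a group.

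PVRL4 was lower in every PVRL4 siRNA library than in every control library. The gene (amplicon AMPL14719304) lies on the minus strand of chromosome 1, 161070995 to 161089599 in GRCh38. Control libraries held 9.81 ± 1.89 RPM, siRNA 1 libraries 5.01 ± 0.866 RPM and siRNA 2 libraries 2.96 ± 0.411 RPM (SD, n = 3 each), so that 51.0% and 30.2% of the control level remained. These levels rest on 83 to 118 reads per control library, 45 to 62 with siRNA 1 and 27 to 34 with siRNA 2. With siRNA 2 PVRL4 fell by 1.44 on the log2 scale (95% confidence interval -1.85 to -1.03, limma adjusted p = 0.00224). With siRNA 1 the change was -0.84 (interval -1.25 to -0.43) and missed the threshold (limma adjusted p = 0.0601; edgeR 0.0551), passing it with the replicate block (adjusted p = 0.0132). The levels under the 2 siRNAs differed by -0.60, short of the threshold (limma adjusted p = 0.126) past it with the replicate block in limma (0.0383) and short of it with the block in edgeR (0.0543). An exact two-sided permutation test gave p = 0.1 for each comparison, the smallest that 3 against 3 libraries allow.

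**Figure D1:**
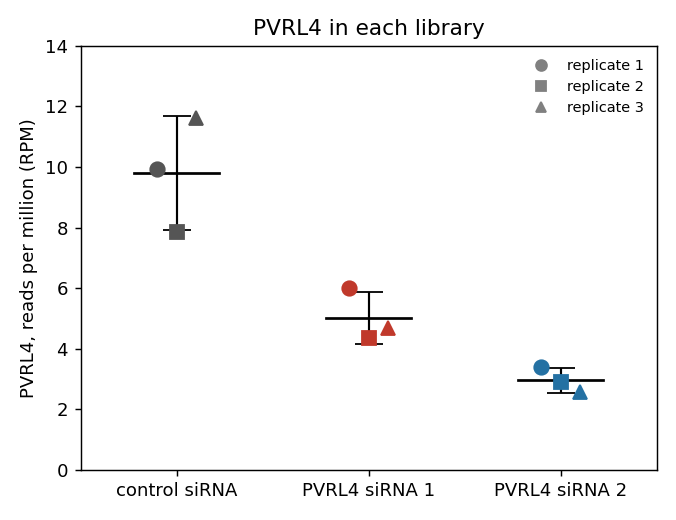
PVRL4 in RPM in each of the 9 libraries, by group; symbols mark the replicate number, the horizontal line the group mean and the bar its SD. The 3 control libraries lie between 7.86 and 11.6 RPM, above all 6 PVRL4 siRNA libraries, of which the highest holds 5.99 RPM.

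The receptor genes ERBB2 and ERBB3 and the FOS family genes FOS and FOSL2 did not pass the threshold against control with either siRNA. FOSB, FOSL1 and JUN were too low to be tested. ERBB2, the amplified receptor tyrosine kinase gene, was at 804 ± 83.9 RPM in control, 843 ± 105 with siRNA 1 and 665 ± 101 with siRNA 2 (SD, n = 3). ERBB3, its dimerization partner, was at 153 ± 21.1, 131 ± 21.1 and 150.3 ± 20.5 RPM. Of the FOS family, which form AP-1 transcription factors with JUN proteins, FOSL2 was at 20.3 ± 3.27, 21.5 ± 4.44 and 20.04 ± 3.33 RPM and FOS at 1.12 ± 0.457, 1.15 ± 0.636 and 0.878 ± 0.118 RPM. FOSB stayed under the filter of 1 RPM, at means of 0.519 to 0.635 RPM, while FOSL1 and JUN were below the floor of 3 reads in mean. The log2 changes of FOS with siRNA 1 (0.0047) and of ERBB3 (-0.024) and FOSL2 (-0.02) with siRNA 2 changed sign under median-of-ratios scaling, and the first also under TMM and quantile scaling, as did that of FOSL2 with siRNA 2. They also changed sign without control replicate 3 (FOS -0.19, ERBB3 0.082), siRNA 2 replicate 1 (ERBB3 0.079), control replicate 2 (FOSL2 0.10) or siRNA 2 replicate 3 (FOSL2 0.099). Those of ERBB2 (0.065) and FOSL2 (0.067) with siRNA 1 changed sign with 1 library left out: ERBB2 without control replicate 1 (-0.022) or siRNA 1 replicate 2 (-0.0013), and FOSL2 without control replicate 1 (-0.0056), siRNA 1 replicate 1 (-0.025) or siRNA 1 replicate 2 (-0.018). Among the 9 tested AP-1 family genes limma called 0 with either siRNA (2 and 0 at an unadjusted p under 0.05; 0 and 0 by edgeR and by DESeq2), and camera gave adjusted p = 0.323 for siRNA 1 and 0.974 for siRNA 2. With siRNA 2 the median (-0.02) and mean (-0.05) of that list were below 0 while the direction of its camera statistic was up.

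Cells given siRNA 1 showed a strong type I interferon response. IFIT1, an antiviral protein that binds foreign RNA, went from 0.0973 ± 0.0985 RPM in control to 275 ± 280 RPM, a log2 change of 7.32. MX1, a dynamin-like GTPase that blocks viruses, went from 0.353 ± 0.0603 to 325 ± 339 RPM (7.21), and the ubiquitin-like modifier ISG15 from 2.70 ± 0.337 to 314 ± 285 RPM (5.89). The oligoadenylate synthetases OAS2 (6.36) and OAS1 (5.73), which sense double-stranded RNA, rose as well, as did IFIT2 (5.31), IFI6 (4.76, from 28.1 ± 4.41 to 981 ± 732 RPM) and IFI27 (4.74); the 8 limma adjusted p lay between 0.000107 and 0.00328.

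Of the 35 tested genes of the type I interferon list, 30 rose past the threshold (35 adjusted over the list alone) and 0 fell, with a median log2 change of 3.48 (camera adjusted p = 7.32e-104). With an estimated correlation, which was 0.899 for this list, the adjusted p was 0.141, since its members moved together from library to library, and fry gave 0.0609. The size of these changes depends on how low control values are treated. The list's median was 2.15 at a pseudocount of 5, 5.14 at a pseudocount of 0.1, 6.06 by edgeR and 6.14 by DESeq2, and over the alternatives IFIT1 ranged from 5.15 to 11.4, IFIT2 from 3.32 to 9.85 and IFI27 from 2.79 to 7.85. IRF9, the DNA-binding subunit of a transcription factor of interferon signalling, rose by 3.67. The response differed in size between the 3 libraries: the summed RPM of the list was 9036, 1591 and 4378 in replicates 1, 2 and 3 of siRNA 1, against 403, 431 and 420 in the control libraries. Between 27 and 34 list members were called when any 1 of the 9 libraries was left out. Of the leukocyte markers, 8 (PTPRC and LYZ among them) summed to at most 0.374 RPM in these libraries. That sum leaves out CD68 and CORO1A, which these cells express: CD68 was at 61.4 RPM in control and 82.8 RPM with siRNA 1, and CORO1A at 41.6 and 50.9 RPM.

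**Figure D2:**
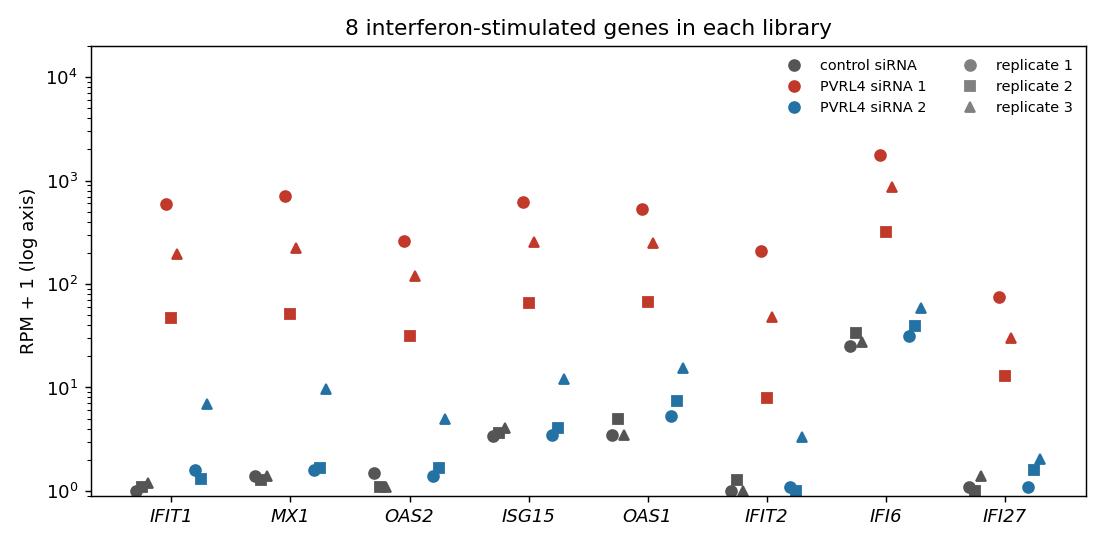
RPM + 1 on a log axis for the 8 interferon-stimulated genes with the largest rise under siRNA 1, in each library; colour gives the group and the symbol the replicate number. In each gene the 3 siRNA 1 libraries lie above the 6 other libraries, with replicate 1 highest and replicate 2 lowest of the siRNA 1 libraries.

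Antigen presentation genes moved with the interferon genes under siRNA 1. Of 13 tested, 3 rose (12 adjusted over the list alone; 8 over all genes with the replicate block): B2M, the light chain of class I molecules (0.77, from 533 to 928 RPM), the peptide transporter gene TAP1 (1.4996) and the immunoproteasome subunit gene PSMB9 (1.57). Camera gave adjusted p = 1.19e-18, and 0.471 with an estimated correlation. With 1 library left out (adjusted p in brackets), B2M lost its call without control replicate 1 (0.162), control replicate 2 (0.0568), control replicate 3 (0.0990), siRNA 1 replicate 1 (0.0666) or siRNA 1 replicate 3 (0.0732). TAP1 lost it without control replicate 1 (0.148), control replicate 2 (0.108), control replicate 3 (0.170), siRNA 1 replicate 3 (0.0799), siRNA 2 replicate 2 (0.0639) or siRNA 2 replicate 3 (0.0525), and PSMB9 without control replicate 1 (0.135), control replicate 2 (0.148), control replicate 3 (0.177), siRNA 1 replicate 1 (0.148), siRNA 1 replicate 3 (0.140), siRNA 2 replicate 1 (0.0591), siRNA 2 replicate 2 (0.0648) or siRNA 2 replicate 3 (0.0539). Of the 12 NF-kappaB and inflammatory genes 1 rose (1 adjusted over the list alone), the chemokine gene CCL5 (3.08, from 0.224 to 12.4 RPM; camera adjusted p = 0.000689, 0.846 with an estimated correlation).

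Cell cycle genes shifted slightly the other way as lists under siRNA 1. None of the 30 mitosis genes passed by limma, edgeR or DESeq2 (0 adjusted over the list alone; 2 lower at an unadjusted p under 0.05), but 28 had a negative sign, with a median of -0.15 (camera adjusted p = 4.42e-06, 0.876 with an estimated correlation). The centromere genes CENPA and CENPF had changes of -0.33 and -0.28. For 34 S phase genes limma called 0 (0 adjusted over the list alone, 0 at an unadjusted p under 0.05, 0 by edgeR and DESeq2), with a median of -0.089 (camera adjusted p = 0.0431, 0.996 with an estimated correlation); RRM1 and UHRF1 had changes of -0.21 and -0.35. Of 17 immediate early and ERK feedback genes limma called 0 (0 adjusted over the list alone, 3 higher at an unadjusted p under 0.05, 0 by edgeR, 1 by DESeq2, 1 with the replicate block), and camera placed the list up (adjusted p = 0.00468, 0.876 with an estimated correlation). Its leading members were the phosphatase gene DUSP1 (0.78, adjusted p = 0.337, 0.00993 with the replicate block) and IER3 (0.36). The other 30 lists tested had adjusted p of 0.182 to 0.991.

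The genes that fell with siRNA 1 changed far less than the interferon genes rose. JAK1, a kinase of interferon and cytokine receptors, fell from 147 ± 10.3 to 81.2 ± 7.52 RPM (-0.86, limma adjusted p = 0.00064). TUG1, a long noncoding RNA, fell from 168 ± 7.37 to 101 ± 1.67 RPM (-0.73, adjusted p = 0.000809). FAM63B, a deubiquitinase gene, fell from 16.2 ± 1.42 to 7.73 ± 2.28 RPM (-1.01), and ERCC6L, a helicase gene of mitotic chromosomes, from 18.4 ± 2.14 to 9.49 ± 0.770 RPM (-0.89). MESDC2, a chaperone gene of lipoprotein receptors (-0.84), the nuclear receptor gene PPARD (-0.81), the mannosyltransferase gene DPY19L3 (-0.71) and NAPG (-0.70), a gene of vesicle fusion, completed the 8 largest falls. JAK1, TUG1 and PPARD passed the threshold with each library left out. ERCC6L lost the call without control replicate 1 (0.0763) and MESDC2 without control replicate 3 (0.05001). FAM63B lost it without control replicate 1 (0.0816), control replicate 3 (0.0813), siRNA 1 replicate 1 (0.0649) or siRNA 1 replicate 3 (0.0668). DPY19L3 lost it without control replicate 1 (0.0526), control replicate 2 (0.0569), control replicate 3 (0.099797), siRNA 1 replicate 1 (0.0745) or siRNA 1 replicate 3 (0.0559), and NAPG without control replicate 1 (0.214), control replicate 2 (0.147), control replicate 3 (0.0519), siRNA 1 replicate 1 (0.137) or siRNA 1 replicate 3 (0.144).

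Across all 11158 genes, 71 rose and 24 fell with siRNA 1 (130 and 76 with the replicate block, 84 and 24 by edgeR). Of the 71, 34 belonged to a list, and 37 did not. The 37 included DDX60, IFI35, IFITM3 and GBP1, named after the calls were seen. The split therefore follows the lists as written and does not measure how many rises lay outside the interferon response. No library of 1 group overlapped the other group, in the direction given, for 6.40% (higher) and 5.59% (lower) of genes. For independent libraries chance gives 10% for both directions together. The replicate numbers pair these libraries across groups, so the share by chance may be lower here. The counts were 40 and 6 without control replicate 1, 44 and 11 without control replicate 2, and 41 and 8 without control replicate 3. They were 8 lower without siRNA 1 replicate 1, 119 higher without siRNA 1 replicate 2, and 43 and 13 without siRNA 1 replicate 3. The number of lists called was 6, and 3 without control replicate 1; fry called 0.

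With siRNA 2 most changes were falls. HIBADH, an enzyme of valine breakdown on chromosome 7, fell from 328 ± 20.98 to 133 ± 41.9 RPM (-1.35, limma adjusted p = 0.00497). PVRL2 (NECTIN2), another nectin adhesion gene, on chromosome 19 at 44846175 to 44889228 in GRCh38, fell from 34.9 ± 2.08 to 13.7 ± 2.90 RPM (-1.30, adjusted p = 0.000603). SLC25A24, a mitochondrial carrier gene, fell from 116 ± 7.99 to 50.6 ± 5.96 RPM (-1.19). MPHOSPH6, an RNA exosome factor gene (-1.16), the galactosyltransferase gene B4GALT4 (-1.16), LCLAT1, an acyltransferase gene (-1.12), and AIDA (-1.12) followed. These 7 genes passed the threshold with each library left out. With siRNA 1 none of the 7 passed the threshold, and for each of them the difference between the siRNAs did (adjusted p between 0.000141 and 0.00450). PVRL2 was at 35.4 ± 2.12 RPM with siRNA 1.

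Only 4 genes rose with siRNA 2. CRYAB, a small heat shock protein gene, rose from 6.53 ± 1.61 to 20.1 ± 6.04 RPM (1.47, limma adjusted p = 0.0158). The adhesion molecule gene MCAM rose from 9.68 ± 1.75 to 21.9 ± 7.35 RPM (1.07), the heme oxygenase gene HMOX1 from 29.9 ± 2.39 to 59.0 ± 10.7 RPM (0.94) and the phosphatase gene PHLPP2 from 78.7 ± 7.003 to 119 ± 7.23 RPM (0.59). Each of these calls was lost with some library left out (adjusted p in brackets). For CRYAB this was control replicate 1 (0.0967), control replicate 2 (0.0750) or siRNA 2 replicate 2 (0.0557). For MCAM it was control replicate 1 (0.143), control replicate 2 (0.188), control replicate 3 (0.0622), siRNA 2 replicate 1 (0.104) or siRNA 2 replicate 2 (0.117), and for HMOX1 control replicate 1 (0.0665), control replicate 2 (0.0750), control replicate 3 (0.0930), siRNA 2 replicate 1 (0.0805) or siRNA 2 replicate 2 (0.0640). For PHLPP2 it was control replicate 1 (0.0891), control replicate 2 (0.205), control replicate 3 (0.148), siRNA 1 replicate 3 (0.0619), siRNA 2 replicate 1 (0.0912), siRNA 2 replicate 2 (0.131) or siRNA 2 replicate 3 (0.0823).

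**Figure D3:**
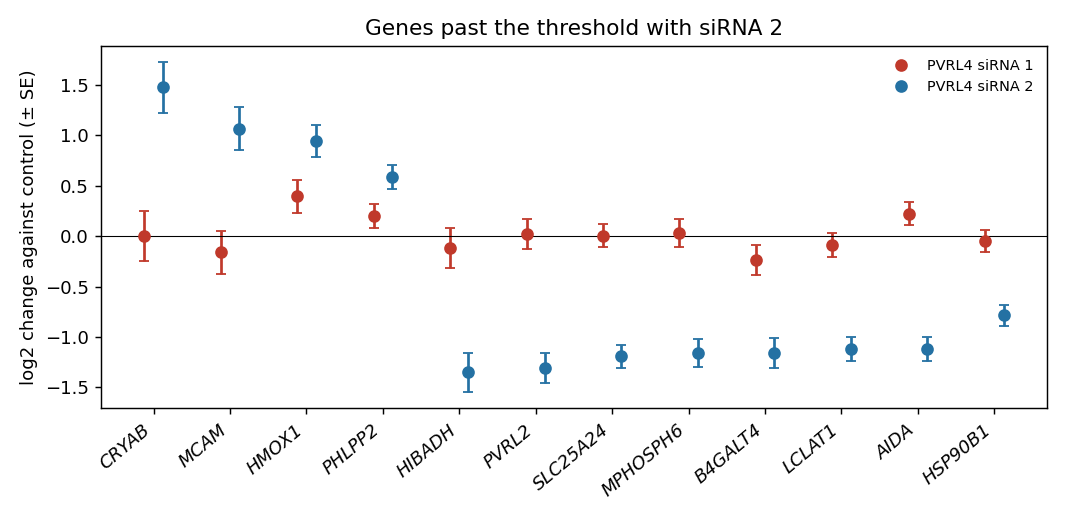
Log2 change against control with its SE for the 11 genes named for siRNA 2 and for HSP90B1, under siRNA 1 (red) and siRNA 2 (blue). With siRNA 2 the values run from 1.47 for CRYAB to -1.35 for HIBADH; none of these 12 genes passed the threshold with siRNA 1.

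Secretory pathway genes were among those lower with siRNA 2. Of 20 ER chaperone and unfolded protein response genes 3 fell (3 adjusted over the list alone) and 0 rose. HSP90B1, the ER-resident HSP90 chaperone, fell from 2075 to 1212 RPM (-0.78, limma adjusted p = 0.00245), CRELD2 by 0.59 and EDEM1, a factor of ER-associated degradation, by 0.60. Camera gave adjusted p = 0.00187 (0.197 with an estimated correlation), and fry 0.00527. CRELD2 lost the call without control replicate 1 (0.109), control replicate 2 (0.0874), control replicate 3 (0.0579), siRNA 2 replicate 1 (0.0817) or siRNA 2 replicate 2 (0.0545), and EDEM1 without control replicate 1 (0.109), control replicate 2 (0.158), control replicate 3 (0.103), siRNA 2 replicate 1 (0.0966) or siRNA 2 replicate 3 (0.0545). By edgeR EDEM1 was at adjusted p = 0.0531. Of 22 cholesterol synthesis genes limma called 0 (0 adjusted over the list alone, 6 lower at an unadjusted p under 0.05, 0 by edgeR, 1 lower by DESeq2, 3 lower with the replicate block), with camera adjusted p = 0.00411 for the downward shift (0.691 with an estimated correlation). Of its members, CYP51A1 had a change of -0.42.

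Luminal epithelial genes were also low as a list with siRNA 2. Of 20, limma called 0 (5 lower adjusted over the list alone, 7 lower at an unadjusted p under 0.05, 0 by edgeR, 1 lower by DESeq2), 18 had a negative sign and the median was -0.20 (camera adjusted p = 0.000627, 0.452 with an estimated correlation). EHF, an epithelial ETS factor gene, was at -0.59 (adjusted p = 0.0512, 0.00377 with the replicate block) and the keratin gene KRT8 at -0.38 (0.250, 0.0155 with the block); with the block 5 members fell. Of 17 immediate early and ERK feedback genes limma called 0 (0 adjusted over the list alone, 4 lower at an unadjusted p under 0.05, 0 by edgeR and DESeq2, 1 lower with the block), with camera adjusted p = 0.0413 for the downward shift (0.787 with an estimated correlation); DUSP6 and SPRED1 had changes of -0.68 and -0.38.

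Small upward shifts were called for 5 lists with siRNA 2. Of 14 heat shock genes 1 rose (1 adjusted over the list alone), CRYAB (camera adjusted p = 0.0237, 0.691 with an estimated correlation). In the 4 other lists limma, edgeR and DESeq2 called 0 members, and 0 adjusted over the list alone. They were 12 NF-kappaB genes (2 higher at an unadjusted p under 0.05, camera adjusted p = 0.00373, led by NFKB2 at 0.28 and SOD2 at 0.23), 35 interferon genes (0 at an unadjusted p under 0.05, 0.00411, OAS1 at 1.11 and STAT2 at -0.43), 29 oxidative phosphorylation genes (0 at an unadjusted p under 0.05, 0.0233, NDUFA4 at 0.30) and 13 antigen presentation genes (2 higher at an unadjusted p under 0.05, 0.0233, B2M at 0.35 and PSMB9 at 0.72). With an estimated correlation their adjusted p were 0.691, 0.787, 0.787 and 0.787. The interferon list's median was 0.29, and 0.069 without siRNA 2 replicate 3, whose summed RPM over the list was 609 against 431 and 460 in siRNA 2 replicates 1 and 2. S phase genes and replication-dependent histone genes passed only with the replicate block (camera adjusted p = 0.0376 and 0.0343, against 0.0754 and 0.104, and 0.787 for both with an estimated correlation), and the other lists had adjusted p of 0.0598 to 0.974 without it. Within lists that were not called, the nectin and adherens junction list held 1 gene that fell (PVRL2) among 15 (2 adjusted over the list alone, 3 over all genes with the block), with camera adjusted p = 0.104.

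In total 4 genes rose and 72 fell with siRNA 2 (51 and 329 with the replicate block, 5 and 53 by edgeR, 278 and 773 at an unadjusted p under 0.05). Non-overlapping groups were seen for 4.99% (higher) and 8.95% (lower) of genes, where chance gives 10% for both directions if libraries are independent. Falls numbered 18, 21 and 27 without control replicate 1, 2 or 3, and 29 and 33 without siRNA 2 replicate 1 or 3. The rises went to 0 without control replicate 1, control replicate 2 or siRNA 2 replicate 2, and to 1 without siRNA 2 replicate 1. Of 36 lists 9 were called (5 up, 4 down), and 5 without siRNA 2 replicate 3; fry called 1, the ER chaperone list.

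The 2 siRNAs were also set against each other, since both target PVRL4 and differ in sequence. Interferon genes had the largest median change among the lists tested: 31 of 35 were lower with siRNA 2 than with siRNA 1 (34 adjusted over the list alone), among them IFIT1 (-6.17), MX1 (-6.08), OAS2 (-5.46), ISG15 (-5.29), IFIT2 (-4.81), OAS1 (-4.62), IFI27 (-4.34), IFI6 (-4.23) and IRF9 (-3.43), with camera adjusted p = 4.93e-51 (0.350 with an estimated correlation, fry 0.0480). CD274, which encodes the immune checkpoint ligand PD-L1, was at 2.78 RPM in control, 8.43 RPM with siRNA 1 and 2.47 RPM with siRNA 2. Between the siRNAs its change was -1.34 (limma adjusted p = 0.0155). Of 13 antigen presentation genes it was the 1 called (9 adjusted over the list alone, 6 over all genes with the block). Camera gave adjusted p = 2.84e-06 for that list, and 0.867 with an estimated correlation. On the other side were CRYAB (1.47), MCAM (1.23), the transcription factor gene KLF11 (0.98, from 51.2 ± 0.942 to 102 ± 7.45 RPM), ERCC6L (0.91), JAK1 (0.89), the centriole gene CCP110 (0.88), NAPG (0.85) and the ceramide kinase gene CERK (0.83). Against control, KLF11, ERCC6L, JAK1, CCP110 and NAPG were among the genes that fell with siRNA 1, and CRYAB and MCAM among those that rose with siRNA 2. CERK lost its call without siRNA 1 replicate 1 (0.0741), siRNA 2 replicate 2 (0.0669) or siRNA 2 replicate 3 (0.0788).

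Proliferation and growth-signalling lists also differed between the siRNAs. Of 17 immediate early and ERK feedback genes 3 were lower with siRNA 2 than with siRNA 1 (6 adjusted over the list alone, 9 over all genes with the block): the transcription factor gene EGR1 (-0.78), the RAS-ERK inhibitor gene SPRED1 (-0.58) and IER3 (-0.53), with camera adjusted p = 6.02e-05 (0.867 with an estimated correlation). EGR1 lost the call without siRNA 1 replicate 1 (0.0689), siRNA 1 replicate 2 (0.0680), siRNA 1 replicate 3 (0.0901), siRNA 2 replicate 1 (0.0632) or siRNA 2 replicate 3 (0.0828). SPRED1 lost it without control replicate 1 (0.0503), control replicate 3 (0.0567), siRNA 1 replicate 1 (0.111), siRNA 1 replicate 2 (0.108), siRNA 1 replicate 3 (0.0985), siRNA 2 replicate 1 (0.111) or siRNA 2 replicate 3 (0.112), and IER3 without control replicate 2 (0.0508), siRNA 1 replicate 1 (0.122), siRNA 1 replicate 2 (0.0698), siRNA 1 replicate 3 (0.105), siRNA 2 replicate 1 (0.125) or siRNA 2 replicate 3 (0.119). By edgeR IER3 was at adjusted p = 0.0577. Mitosis and S phase genes were higher as lists with siRNA 2. Of the 30 and 34 genes limma called 0 and 0 (0 and 0 adjusted over the list alone and by edgeR, 1 and 1 by DESeq2, 5 and 6 higher at an unadjusted p under 0.05), with camera adjusted p = 1.2e-05 and 0.000956 (0.867 for both with an estimated correlation). With the block 5 mitosis and 3 S phase genes passed, among them CDK1 (0.45, adjusted p = 0.0945, 0.00848 with the block), CENPF (0.33, 0.195, 0.0297), E2F1 (0.40, 0.130, 0.00709) and E2F2 (0.44, 0.155, 0.0205).

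Of the 20 ER chaperone genes, 3 were lower with siRNA 2 than with siRNA 1 and 17 were not called (3 adjusted over the list alone); this comparison and the one against control share the siRNA 2 libraries. The 3 were HSP90B1 (-0.74), CRELD2 (-0.56) and EDEM1 (-0.53), with camera adjusted p = 0.00642 (0.350 with an estimated correlation) and fry 0.00439. CRELD2 lost its call without siRNA 1 replicate 1 (0.0528), and EDEM1 without siRNA 1 replicate 1 (0.0746), siRNA 1 replicate 2 (0.0753), siRNA 1 replicate 3 (0.0726) or siRNA 2 replicate 1 (0.0854). Of 20 luminal genes 1 was lower, EHF (-0.54; 6 adjusted over the list alone, 7 with the block; camera adjusted p = 0.00642, 0.801 with an estimated correlation); its call was lost without control replicate 3 (0.0508), siRNA 1 replicate 2 (0.144), siRNA 1 replicate 3 (0.109), siRNA 2 replicate 1 (0.0907) or siRNA 2 replicate 3 (0.106). Of 22 cholesterol synthesis genes limma called 0 (0 adjusted over the list alone, 4 lower at an unadjusted p under 0.05, 0 by edgeR and DESeq2), with camera adjusted p = 0.0148 (0.867 with an estimated correlation); with the block 4 were lower, among them CYP51A1 (-0.45, adjusted p = 0.101, 0.0251 with the block and 0.0541 with the block in edgeR). Oxidative phosphorylation and replication-dependent histone lists passed only with the block (0.0492 and 0.0193, against 0.0504 and 0.108, and 0.867 for both with an estimated correlation). Other lists had adjusted p of 0.0504 to 0.961 without the block.

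Between the siRNAs 66 genes were higher and 274 lower with siRNA 2 (314 and 727 with the replicate block, 87 and 257 by edgeR, 564 and 1122 at an unadjusted p under 0.05). Of these, 64 of the higher and 224 of the lower genes belonged to no list. Quantile normalization gave a split of 104 higher and 228 lower. Without siRNA 1 replicate 1, 2 or 3 the higher genes numbered 24, 34 and 26, and without siRNA 2 replicate 1 or 2 they numbered 27 and 35. The lower genes numbered 129 and 153 without siRNA 1 replicate 1 or 3, and 164 and 176 without siRNA 2 replicate 1 or 3. Groups did not overlap for 7.04% (higher) and 12.6% (lower) of genes, where chance gives 10% for both directions if libraries are independent. ERBB2 was lower with siRNA 2 than with siRNA 1 by 0.35 on the log2 scale only with the block in limma (adjusted p = 0.0472, against 0.203); with the block in edgeR the adjusted p was 0.0782. Of 36 lists 8 were called (2 up, 6 down); fry called 2, the interferon and ER chaperone lists.

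Genes that follow the target would be changed by both PVRL4 siRNAs, but so could genes shifted by the shared controls or their other supplier. By limma 0 genes rose and 0 fell with both siRNAs, where independent lists of these sizes would share 0.0255 and 0.155 genes. EdgeR also found 0 and 0. PVRL4 itself missed the threshold with siRNA 1 (limma adjusted p = 0.0601). In simulated reads limma found 30% (siRNA 1) and 42% (siRNA 2) of genes changed 1.5-fold. The counts of 0 therefore do not show that no gene follows PVRL4. With the replicate block 2 rose (GRHPR and SNORA7B) and 5 fell (FAM49A, H19, PVRL4, SENP5 and TGFBR1), against 0.594 and 2.24 for independent lists. Without control replicate 3, 1 gene rose with both (SNORA7B). These genes outside the naming rule were chosen after their values were seen. Of the 71 genes that rose with siRNA 1, 54 had a positive sign with siRNA 2, at a median log2 change of 0.22 against 2.47. For the interferon list the siRNA 2 median was 0.29, and 0.069 without siRNA 2 replicate 3. Of the 72 that fell with siRNA 2, 42 had a negative sign with siRNA 1, at a median of -0.03 against -0.73. Both contrasts share the control libraries, which alone favours equal signs. Tests of the difference itself were passed by 64 of the 71 and 66 of the 72. The genes were chosen through siRNA libraries that these tests use again, so a high share was favoured by the choice.

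Across genes, the log2 changes of the 2 siRNAs correlated at 0.232 (Pearson; Spearman 0.225), with the same sign in 57.2%; genes are not independent replicates. In 100 simulations of unchanged groups that share these 3 controls the correlation was 0.499 and the same sign appeared in 66.6%. Shared controls alone give such a correlation, and changes specific to a siRNA lower it. The correlation and the share of signs therefore cannot tell whether the siRNAs act alike. The observed covariance was 0.0163, against 0.0173 in the simulations (0.0162 to 0.0190), a difference of -0.00096. These simulations took the spread between libraries of a group, which includes differences between replicate numbers. The numbers pair the libraries across groups, so such differences partly cancel in the contrasts, and this simulated covariance may be too high. When the spread was taken from the fit with the replicate block, the simulated covariance was 0.0108 (0.0102 to 0.0115) and the difference 0.00546. The observed covariance lay above that range, and the cause was not tested.

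**Figure D4:**
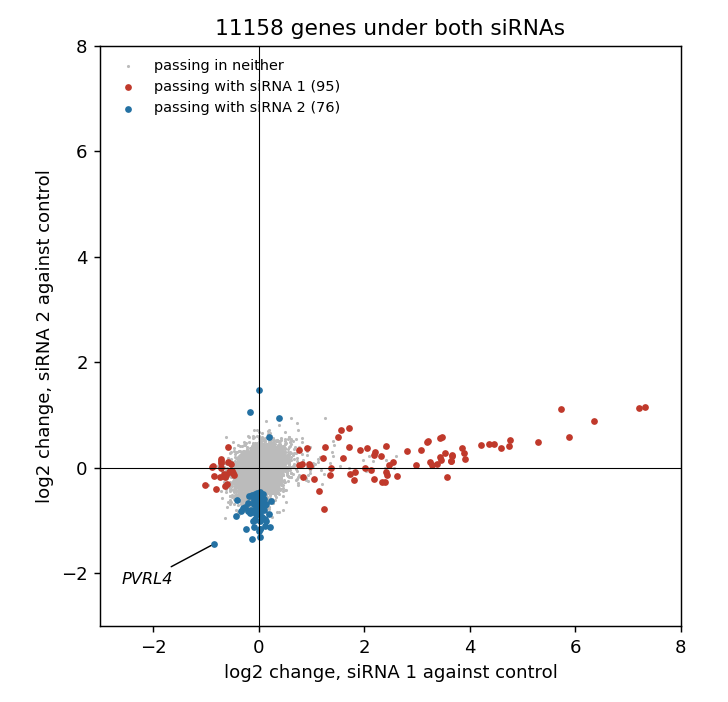
Log2 change against control of the 11158 tested genes with siRNA 1 (horizontal) and siRNA 2 (vertical); red and blue points mark the 95 and 76 genes past the threshold with siRNA 1 and siRNA 2. No gene passed with both, and PVRL4 lies at -0.84 and -1.44.

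When the 6 PVRL4 siRNA libraries were pooled against control, limma called 0 higher and 0 lower genes (176 and 235 at an unadjusted p under 0.05; edgeR 0 and 0; DESeq2 3 and 1). The genes called by DESeq2 were IFIT1, MX1 and OAS2, higher, and PVRL4, lower. Averaging the 2 siRNA contrasts in the 3-group fit, in which the spread within each siRNA is separate from the difference between them, called 12 higher and 5 lower genes. The 12 were interferon-stimulated genes, such as IFIT1 and MX1, and the 5 were PVRL4, CBFB, LCLAT1, SLC25A24 and TUG1. Such an average can pass when 1 siRNA alone moves a gene, so these calls do not show a change common to both. None of the 12 was among the 4 genes that rose with siRNA 2. Against control TUG1 was called only with siRNA 1, and PVRL4, CBFB, LCLAT1 and SLC25A24 only with siRNA 2.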

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

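The tests of loss of PVRL4 and of carry-over between libraries, and the form of the carry-over test, were chosen only after the results they bear on were seen. The 3 siRNA groups hold 3 libraries each, which is too few for a test of single outlying samples.

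The 2 PVRL4 siRNAs differed from each other in more genes than either differed from control: 66 genes were higher and 274 lower with siRNA 2 than with siRNA 1. Of the genes that rose with siRNA 1, 64 differed between the siRNAs, and of those that fell with siRNA 1, 15 did. Of the genes that fell with siRNA 2, 66 differed. In the type I interferon list 31 genes differed. These are tests of the difference itself, not of a call in one group and its absence in the other. For genes chosen by their change with 1 siRNA, the tests use the libraries of that siRNA again. A high share among them was therefore favoured by the choice.

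Reads of 5 genes under the expression filter were highest in a siRNA 1 library. In single siRNA 1 libraries CXCL11 reached 33 reads, IFI16 41, IFNB1 24 and SAMD9L 62 (replicate 1), and SP110 36 (replicate 3), with 0 or 1 reads in each control library. IFNB1, the gene of interferon beta itself, had 24, 0 and 6 reads in siRNA 1 replicates 1, 2 and 3 and 0 in each siRNA 2 library. CXCL11 had 4 reads in siRNA 1 replicate 2, against 7, 4 and 1 in the siRNA 2 libraries, so neither gene kept the groups apart. These genes were not part of the tests above.

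The interferon response of the siRNA 1 libraries was weighed first. Loss of PVRL4 as its whole cause is argued against by siRNA 2, which left less PVRL4 and moved the list by a median of 0.29 against 3.48. Leukocyte RNA is argued against by a sum of 8 leukocyte transcripts, PTPRC among them, of at most 0.374 RPM in a siRNA 1 library (CD68 and CORO1A, which the control cells express, are not in that sum), and scaling by a move of the list's median of 0.0158 under median-of-ratios scaling. A direct response to the siRNA 1 duplex or its preparation may explain the pattern, and it was not tested; the control siRNA came from another supplier, and both PVRL4 siRNAs from the same one. No library received siRNA 1 together with restored PVRL4, so a joint effect stays open.

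The low level of interferon genes in siRNA 2 replicate 3 was weighed next. Carry-over of 3.62% of siRNA 1 replicate 3 could account for much of it: over 14 genes the chi-square per degree of freedom was 1.96, against 3.51 and 2.93 for the profiles of siRNA 1 replicates 1 and 2, and against 1.77 as the 95th percentile of counting noise. BST2, outside the 14, was 57.5 RPM above control (32.7 ± 9.04 RPM), where that share predicts 15.9 RPM. A first form of this test, on the SD of the log2 share over 16 genes, gave 1.26, above the 0.554 between siRNA 1 replicates 2 and 1, which argued against carry-over; the test and its thresholds were replaced after that value was seen, because genes with a high control level entered it. Carry-over and a weak response of the cells cannot be told apart for this library.

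Other splits of the same libraries were counted. For siRNA 1 against control 1 of 10 splits, the real one, gave as many genes (95, highest other 0), for siRNA 2 against control 1 of 10 (76, highest other 0) and for siRNA 2 against siRNA 1 1 of 10 (340, highest other 0). These splits are too few for a share under 0.05; 4 of the 10 part as many replicate pairs as the real one. For the pooled comparison the real count is 0, so that 84 of 84 splits give at least as many by construction, and this says nothing about chance. The highest other, 189, sets the 3 siRNA 2 libraries against the rest, which is a treatment group of the design and not a random split. There, 27 splits part as many pairs, and the highest among those that part fewer is 49. For genes called with both siRNAs the real count is also 0, so that 100 of 100 splits drawn from 840 give at least as many by construction (highest other 79 among the 19 that part as many pairs, 68 among those that part fewer).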

How the results depend on the processing

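The edgeR fit with the replicate block was chosen only after the data were seen. Of the values tested again for counts, lists, PVRL4 and the covariance, 238 kept their side, 98 moved and 5 became stronger. Of 95 results for named genes 61 were called; 38 of them kept each call and 23 lost one under some alternative, and 10 of the 34 not called were called under some alternative. Of their 2081 values 1882 kept direction and side, 146 fell short of the threshold and 24 changed sign. No scaling moved the median of all genes by over 0.1. Where no cause is named, the cause was not tested.

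Counts below are higher and lower genes for siRNA 1, siRNA 2 and siRNA 2 against siRNA 1. Without the filter they were 42 and 15, 0 and 29, 33 and 164, with more genes tested. Without the trend they were 40 and 9, 0 and 17, 21 and 171. With the replicate block they were 130 and 76, 51 and 329, 314 and 727, with 2 and 5 genes called with both siRNAs and PVRL4 with siRNA 1 called at -0.84; the block changed no other call beyond those given beside the results. With edgeR and the block they were 137 and 82, 66 and 254, 412 and 603, with 2 and 4 for both and PVRL4 called at -0.98. DESeq2 gave 108 and 53, 23 and 136, 182 higher for siRNA 2 against siRNA 1, 1 lower with both, 3 and 1 pooled, and PVRL4 with siRNA 1 called at -0.99. Fits on the 6 libraries compared gave 2 and 32 for siRNA 2, and 28 higher for siRNA 2 against siRNA 1, with fewer libraries for the spread. At an absolute log2 change of at least 1, 1 gene was lower with siRNA 1, 2 and 11 were called with siRNA 2, and 2 and 96 between the siRNAs. At an adjusted p under 0.01 counts were 40 and 7, 0 and 24, 14 and 95, since these settings are stricter.

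Median-of-ratios scaling gave 101 and quantile normalization 104 higher genes between the siRNAs. Under quantile normalization and a pseudocount of 5, 1 gene fell with both siRNAs and PVRL4 with siRNA 1 was called, at -0.91 and -0.56. The covariance of the log2 changes was 0.0356 at a pseudocount of 0.1 and 0.00682 at 5. The mean of the siRNA contrasts gave 12 and 5 pooled genes. Camera with an estimated correlation called 0, 0 and 0 lists, and fry 0, 1 and 2.

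With 1 library left out, counts ranged from 40 to 119 and 6 to 28 (siRNA 1), 0 to 4 and 18 to 66 (siRNA 2), and 24 to 60 and 129 to 255 (between the siRNAs). Lists called ranged from 3 to 8, 5 to 12 and 7 to 10, genes higher with both siRNAs from 0 to 1 and the covariance from 0.0132 to 0.0253.

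Changes of sign were seen only in genes not called. FOS with siRNA 1 was at -0.0078 (pseudocount 0.1), -0.0018 (median-of-ratios), -0.00072 (TMM), -0.13 (quantile) and -0.19 to 0.20 with 1 library left out. ERBB3 with siRNA 2 was at 0.0063 (median-of-ratios), 0.0057 (edgeR), 0.0023 (edgeR with block), 0.0089 (DESeq2) and -0.12 to 0.082 with 1 library left out. FOSL2 with siRNA 2 was at 0.0094 (median-of-ratios), 0.00062 (TMM), 0.022 (quantile), 0.0070 (edgeR), 0.0040 (edgeR with block), 0.0093 (DESeq2) and -0.13 to 0.10 with 1 library left out. With siRNA 1 and 1 library left out, ERBB2 was at -0.022 to 0.17 and FOSL2 at -0.025 to 0.24. PVRL4 rests on 27 to 118 reads per library, which limits how closely its change can be measured.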

Other observations

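The tests of the other strand of each siRNA, and the genes named in the next paragraph, were chosen only after the results were seen.

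Single genes outside the naming rule also differed between the siRNAs, and whether they belong to a wider shift was not settled. A difference between the siRNAs alone does not say which of them moved a gene away from control. In this paragraph control levels are given only for CD68. The apoptosis, lysosome, Wnt and p53 lists were not called for siRNA 2 against siRNA 1 (camera adjusted p = 0.282, 0.793, 0.775 and 0.793). MCL1, an anti-apoptotic BCL2 family gene, was lower with siRNA 2 than with siRNA 1 (96.0 against 171 RPM, a log2 change of -0.82, limma adjusted p = 0.00556). The Wnt antagonist gene DKK1 (-1.18, 0.0249) and the death ligand gene TNFSF10 (-2.04, from 5.78 to 0.320 RPM, 0.0320) were also lower. The same held for the proton pump gene ATP6V1A (-0.73, 0.0146), the lysosomal gene CD68 (-0.61, 0.0150), the transporter gene ABCC3 (-1.23, 0.0118) and the p53 regulator gene MDM2 (-0.40, 0.0487). CD68 was at 61.4 RPM in control, 82.8 RPM with siRNA 1 and 53.9 RPM with siRNA 2. HSPE1, a mitochondrial chaperone gene, was higher (0.46, 0.0296).

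The genes that fell with each siRNA were weighed for short sequence words in their 3' UTRs, since a siRNA can lower other mRNAs that pair with bases 2 to 8 of its guide strand. For siRNA 1 the word AGTCTGA ranked first of 16164 (t = -11.4 over 10438 genes) and was in 17 of 23 lowered genes (73.9%) against 12.5% of the others. It is also in the 3' UTR of PVRL4, whose mRNA holds 17.7% of the tested words. FAM63B, JAK1, MESDC2, DPY19L3 and NAPG carry AGTCTGA and may be direct off-targets of siRNA 1. The interferon response as a cause of these falls stays open: their change in replicate 1, where the response was highest, differed from that in replicate 2 by a median of -0.21 (interquartile range -0.33 to -0.04), with medians of -0.79, -0.55 and -0.59 in the 3 replicates.

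For siRNA 2 the first word, TGGTCAC (t = -8.75), was in 20 of 70 lowered genes (28.6%) against 10.2% and is not in the PVRL4 mRNA. The bound written beforehand, that such a word would be absent from that mRNA if the seed were not the cause, was too strict, because the end base of a seed need not pair. GGTCACA, which ranked 2 (t = -8.47), is also absent from that mRNA. AGGTCAC, with the same core, ranked 3 (t = -8.42), was in 25 of 70 (35.7%) against 9.36%, and is in PVRL4. It was reached only after TGGTCAC and GGTCACA had failed the bound. The first 6-base word, GGTCAC (65.7% against 23.7%), is in PVRL4 too. That mRNA holds 17.7% of the tested 7-base words, and its share of 6-base words was not counted, so presence there is weak support. AGGTCAC occurs at 2 places in PVRL4, 1283 and 2033. The other strand of a duplex at the first would give ATCCCTT for its bases 1 to 7, which ranked 6 (t = -7.07), and AATCCCT for its bases 2 to 8, which ranked 198 and did not pass. At the second place the corresponding words ranked 16122 and 7542, so the other strand has support at 1 of the 2 places and for 1 of its 2 words. For siRNA 1 the other-strand words at the 2 places of AGTCTGA in PVRL4 ranked 8065, 6774, 11873 and 6176, and none passed. AGGTCAC or ATCCCTT was in 40 of 70 lowered genes (57.1%) against 19.8%. AGTCTGA, TGGTCAC, AGGTCAC, GGTCAC and ATCCCTT passed a Bonferroni threshold of 0.05. Words that went with higher values passed it too, such as TGAACTC for siRNA 1 (t = 4.76) and GGCTCAC for siRNA 2 (t = 5.46). Passing the threshold alone therefore does not mark a seed. HIBADH and LCLAT1 carry AGGTCAC, and AIDA, EDEM1 and PVRL2 carry ATCCCTT, so that the fall of PVRL2 may be an off-target effect; of its 2 transcripts searched only the longer, of 2466 bases, holds that word. Both also hold AGGTCAC at 1 place, outside the 3' UTR searched, and the core GGTCAC at 2.

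These searches read the seeds from the data, since the siRNA sequences were not given in the sources used here. A first form of the search, on log2 changes that were not ranked, also put AGTCTGA first for siRNA 1 and gave the same 3 leading words in another order for siRNA 2. It passed the threshold in 8 of 10 scans of permuted data for siRNA 1, and was replaced by the ranked form.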
